A study of Homo sapiens with 12 samples.

How the data were processed

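RNA of 12 cultures of naive CD4 T cells was measured with the Ion AmpliSeq transcriptome panel (20 ng of RNA) on an Ion Torrent sequencer, per the labels' protocols. The 12 are cells of 4 subjects under 3 treatments: anti-CD3, anti-CD3 with anti-CD28, and anti-CD3 with ICs. The genome build was hg19, per the submitters' processing notes, and the aligner and the counting tool are not given in the sources used here. Libraries were grouped by treatment, and the replicate number is the subject, per the labels.

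The authors deposited a table of 20812 genes whose values are a normalized signal. From the values, each is the number of reads plus 1, multiplied by the mean library total (12186664 reads) over the library's own total. Such values are called scaled reads here, and a gene without reads has a value of 0.780 to 1.44 depending on the library. Whole read counts were recovered from the deposited signal by dividing each value by the worth of 1 read: all 249744 values came out whole within 0.001 (100%). A second deposited table holds ratios of group means and of single libraries, per the file headers, and p-values per gene. Recomputation showed that the deposited p-values equal an equal-variance two-sample test on the scaled reads to within 3.20e-12, with no adjustment for the number of genes. The workbook's other sheets repeat rows of that table for chosen genes, with 0 differing rows.

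The design fixed before the data were examined listed tests for counts, for CPM, TPM and similar units and for log2 values. The unit proved to be a scaled signal, so the branch for normalized values was used: limma 3.58.1 (linear models with an intensity trend and empirical Bayes) in R 4.3.3 on log2(value + 1). A fold change is on that scale, which understates the change of low genes. Genes needed a value of 10 or more in at least 4 libraries. The exact form of this filter was set after the design but before any fit. It left 13679 genes. All 12 libraries entered 1 fit of 3 groups, without a block, and p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05, two-sided. An SE is limma's moderated standard error. The 87 Y-linked and X-inactivation genes were left out of all tests and tables.

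The same replicate number marks the same subject. Correlations of the deviations from group means between libraries of the same number were 0.14 to 0.80, all above 0.1, in the 12 pairs, and in 9 of the 12 the closest library had the same number. The fit with the subject as a block is therefore given beside a result where it changed a call or moved a count by over 1.5 times.

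Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 24 lists, and again with the correlation estimated for each list. With an estimated correlation no list passed in any comparison. Fry, which asks whether the genes of a list move on balance one way, called 0 lists as well. The lists were fixed before the data were examined. They cover Toll-like receptors, heat shock proteins, the interferon response, T cell activation, cytokines, naive genes, the cell cycle, glycolysis, cholesterol synthesis, the unfolded protein response, Fc receptors, E3 ubiquitin ligases, follicular helper genes and helper lineages. They also cover chemokine receptors, metalloproteinases, keratins, ribosomal proteins, stress genes, and markers of monocytes, B cells, cytotoxic cells, CD8 T cells, and platelets and red cells. The keratin, metalloproteinase, Toll-like receptor, heat shock, G-protein-coupled receptor, cytokine and ubiquitin lists were prompted by the names of the workbook's sheets. The study may have chosen those families on these samples, so their direction is not independent evidence.

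Named genes followed a rule fixed before the data were examined. Where no gene passed in a direction, the 4 of smallest p were named as not passing, leaving out names without an official symbol. Not every gene that the rule picks is used here. For each list, the members past the threshold or else the 2 of smallest p could be named. CD28, FCGR3A, FCGR3B, SYK, FCER1G, TLR3, TLR7, TLR8, TLR9, HSPA1A, HSP90AA1, IL2, IFNG, IL2RA, CD69 and BCL6 were always eligible. Other members of the lists, T cell genes, genes of other cell types and the genes that DESeq2 called were named as examples after their values were seen.

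The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 (Wald test). Further alternatives were the subject as a block, no filter, a stricter filter, quantile normalization, median centring, weights per library, pseudocounts of 0.1 and 5, only the 2 groups compared, other thresholds, camera on ranks, and each library or subject left out. Genes with 2 or more exons only, DESeq2, edgeR with the block, the block without ICs replicate 3, and the block with an estimated correlation were added after seeing the data. Exon numbers and gene types came from GENCODE 29, whose build differs from that of the files, so no coordinates were used. Of the table's genes, 19281 (92.6%) matched, and 94.6% of the tested genes had an exon number.

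The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 13679, drawn from the real libraries' means and totals with subject differences. Without the block, limma found 0% of the 2-fold and 28%, 19% and 51% of the 4-fold genes for ICs against anti-CD3, anti-CD28 against anti-CD3 and ICs against anti-CD28, with 0 false calls. With the block it found 15%, 11% and 16% of the 2-fold and 68%, 57% and 75% of the 4-fold genes, with 4, 4 and 8 false calls. Without the block 0.766%, 0.692% and 0.825% of unchanged genes had p under 0.05, so that test is conservative in such data, and with it 4.63%, 5.06% and 5.06%. A list of 30 genes raised by 0.5 on the log2 scale had camera adjusted p of 2.39e-06, 4.27e-06 and 1.12e-06 with the preset correlation and 0.0146, 0.346 and 0.101 with an estimated one. None of the 23 other lists was called, but these held random genes whose counts were drawn independently. The correlation estimated for real lists was 0.777 for the cell cycle, 0.581 for the interferon response and 0.459 for cytotoxic markers. The simulation therefore cannot show how the preset correlation of 0.01 behaves for such lists.

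Depth was 8.49 to 15.6, in units of 1e6 reads, per library. A count of 0 allows up to 3 reads, which is 0.192 to 0.353 RPM (reads per 1e6 reads of the library). Such limits cover counting error only, since amplicon reads without molecular identifiers are not independent molecules. Depths of groups were compared with exact permutation tests, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.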

Results

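RNA was measured in naive CD4 T cells, sorted for CD45RA, from the blood of 4 subjects with systemic lupus erythematosus. Cells of each subject received 3 treatments for 2 days with 20 IU of IL-2, which gave 12 libraries in 3 groups of 4. The first group received an antibody against CD3 (0.25 microgram per ml), which triggers the T cell receptor. The second received anti-CD3 with an antibody against CD28 (2.0 microgram per ml), the classical costimulatory receptor. The third received anti-CD3 with ICs (10 microgram per ml), an abbreviation that the labels do not spell out. The replicate number is the subject in every group. The assay was a targeted amplicon panel of the human transcriptome (20 ng of RNA per library), read on an Ion Torrent sequencer.

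Depth is given in units of 1e6 reads. The anti-CD3 libraries held 10.8, 13.8, 10.9 and 11.5 for replicates 1 to 4, the ICs libraries 10.8, 12.1, 8.49 and 10.6, and the anti-CD28 libraries 14.5, 13.9, 15.6 and 13.2. Mean depth was 11.8 ± 1.42 with anti-CD3, 10.5 ± 1.49 with ICs and 14.3 ± 1.01 with anti-CD28 (SD, n = 4 each). By a two-sided exact permutation test, depth gave p = 0.0286 for ICs against anti-CD28, 0.0571 for anti-CD28 against anti-CD3 and 0.314 for ICs against anti-CD3. Paired by subject the exact p was 0.125 each, the smallest that 4 pairs allow. Values below are scaled reads, the deposited unit, as mean ± SD over the 4 libraries of a group.

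T cell genes were abundant in every library. CD3E, a chain of the T cell receptor complex, was at 9979 ± 2416 with anti-CD3, 10859 ± 3472 with ICs and 8619 ± 2460 with anti-CD28, and CD4 was at 4186 ± 726, 4069 ± 2525 and 5216 ± 1811. Genes of other lymphocytes were also read: GNLY, a cytotoxic granule protein, was at 3436 ± 3400 with anti-CD3, 1503 ± 2339 with ICs and 6989 ± 7852 with anti-CD28. CD8A was at 2434, 573 and 2680 in the anti-CD3, ICs and anti-CD28 libraries of replicate 3, and at 370 or lower in the other 9 libraries. Subjects differed more than treatments: the subject took 60.2% of the variance of the tested genes and the treatment 12.2%. These are raw shares, with no allowance for what arbitrary groups of libraries would take, so the 12.2% does not measure an effect of treatment.

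The library of ICs replicate 3 stood apart in genes that T cells do not use. The 369 olfactory receptor genes of the panel, which encode odorant sensors of the nose, took 12619 RPM there (reads per 1e6 reads of the library), against 26.7 to 1858 with anti-CD3, 39.6 to 643 with anti-CD28, and 70.1, 161 and 1710 in the other ICs libraries. Among genes with at most 3 reads in each library of replicate 1, those with 1 exon had a median of 32.3 RPM in ICs replicate 3. Those with 4 or more exons had 0.118, which is 1 read there. The plot of olfactory receptor reads and silent genes gives all 12 libraries.

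**Figure D1:**
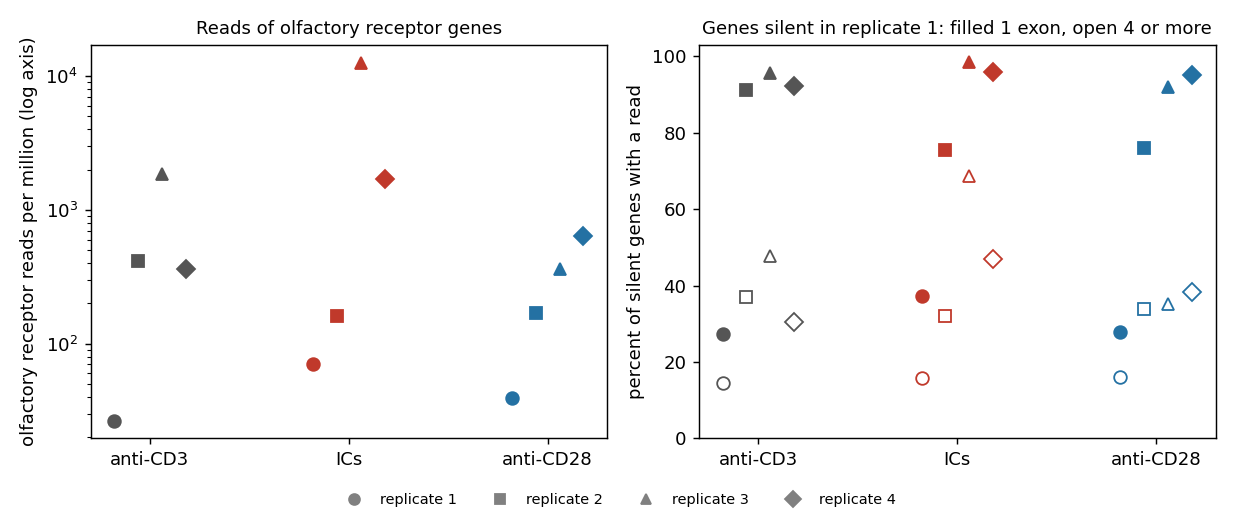
Reads of genes that T cells do not use, in the 12 libraries. Left, RPM of the 369 olfactory receptor genes (log axis). Right, the percent of silent genes (at most 3 reads in each library of replicate 1) that had a read, filled for the 617 genes with 1 exon and open for the 4757 with 4 or more. The ICs library of replicate 3 lies highest in both panels.

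ICs against anti-CD3 asks what ICs added to stimulation through CD3. With ICs, genes of the type I interferon response, the antiviral program that interferon switches on, fell as a group: 33 of 34 were lower, with a median log2 fold change of -0.83 (limma camera adjusted p = 3.41e-11; adjusted p = 0.527 with an estimated correlation). BST2, a membrane protein that tethers budding viruses, was at 2048 ± 96.3 with ICs and 3481 ± 773 with anti-CD3 and was lower in 4 of 4 subjects. MX1, an antiviral GTPase, was at 1289 ± 913 against 2546 ± 1320, and OAS1, a sensor of double-stranded RNA, at 252 ± 106 against 455 ± 125. The median of the list was -0.84, -2.14, 0.21 and -0.33 in subjects 1 to 4, and it was -0.49 without ICs replicate 2. In limma BST2 was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0495), and no member passed over all genes. That call held without anti-CD3 replicate 3 (0.0272) and was lost without any of the other 7 libraries, at 0.0605 to 0.201.

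Markers of natural killer and other cytotoxic cells fell with ICs: 20 of 21 were lower, with a median of -1.78 (camera adjusted p = 3.56e-09; adjusted p = 0.527 with an estimated correlation). PRF1, the pore-forming protein of cytotoxic granules, was at 402 ± 172 with ICs against 1424 ± 879, and NCR1, an activating receptor of natural killer cells, at 7.64 ± 3.61 against 91.2 ± 97.7. TYROBP, an adaptor of natural killer and myeloid receptors, was at 56.0 ± 62.8 against 351 ± 491. The median was -2.19, 0.85, -2.70 and -2.93 in subjects 1 to 4, so subject 2 went the other way. No member passed adjusted over the list alone without the block, and 8 passed with the subject as a block.

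The 8 markers of CD8 T cells moved with the cytotoxic list, with which they share GZMK. CD8A was lower with ICs in each subject, but in subject 2 this was 10 against 15 reads, too few to tell apart. CD8B was lower in subjects 1 (45.1 against 83.2) and 3 (296 against 993) and higher in subjects 2 (27.2 against 7.92) and 4 (63.1 against 37.2). The 8 markers fell with a median of -1.21, 7 of 8 lower (camera adjusted p = 0.0306; 0 members adjusted over the list alone and 2 with the block), and the adjusted p = 0.541 with an estimated correlation. EOMES, a transcription factor of cytotoxic and memory T cells, was at 82.5 ± 46.9 against 468 ± 291. The CD8 call ended without ICs replicate 1 (0.239; median -0.54) or 4 (0.242), and without anti-CD3 replicate 1 (0.151) or 3 (0.219; median -0.67). The Fc receptor and Syk family list holds receptors for antibodies and the kinases behind them. It fell with a median of -0.18 and a mean of -0.55, 17 of 22 lower (camera adjusted p = 0.0306; adjusted p = 0.527 with an estimated correlation). FCGR3A belongs to the cytotoxic list as well, so this fall is not independent of that list. FCER1G, the signalling chain that natural killer and myeloid cells use, was at 91.5 ± 41.6 against 422 ± 540, PLCG2 at 87.5 ± 79.2 against 306 ± 255, and the receptor FCGR3A at 32.3 ± 18.0 against 309 ± 378. Both FCER1G and FCGR3A were highest in anti-CD3 replicate 4 (1231 and 815), without which their log2 fold changes moved from -1.57 to -0.81 and from -1.79 to -0.77, and in subject 2 FCGR3A was higher with ICs (51.4 against 7.04). This call was lost without ICs replicate 3 (0.383) or 4 (0.163), and without anti-CD3 replicate 3 (0.219; median -0.09) or 4 (0.0503), while the median was -0.33 without anti-CD3 replicate 1, -0.30 without ICs replicate 1 and -0.05 in edgeR. With only genes of 2 or more exons, the Fc receptor list had adjusted p = 0.0783 and the CD8 list 0.057, and by ranks the CD8 list had 0.0635. FCGR3B and TLR8 had no read in any ICs library, where 0 reads allow up to 0.248 to 0.353 RPM, and FCGR3B, TLR7 and TLR8 were too low to test.

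Chemokine and other G-protein-coupled receptors of T cells fell with a median of -0.36, 20 of 25 lower (camera adjusted p = 0.0224; adjusted p = 0.298 with an estimated correlation). The list shares CX3CR1 with the cytotoxic list, so its fall is not fully independent of that list. PTGER2, a prostaglandin receptor, was at 218 ± 200 with ICs against 504 ± 186 and was lower in 4 of 4 subjects. Its log2 fold change ran from -2.58 without subject 4 to -1.11 without subject 2. Leaving out ICs replicate 3 (0.236) or 4 (0.0729) or anti-CD3 replicate 1 (0.151) ended the call. No member passed adjusted over the list alone, and 1 passed with the block. In edgeR the median was -0.21.

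Heat shock proteins and stress genes rose as groups with ICs. Of 28 heat shock proteins and chaperones, which refold damaged proteins, 19 were higher, with a median of 0.08 and a mean of 0.42 (camera adjusted p = 0.00784; adjusted p = 0.541 with an estimated correlation). HSPA1A was at 3433, 100646, 63536 and 7794 in ICs replicates 1 to 4, against 5294, 7987, 9403 and 4067 with anti-CD3. HSPA1A and HSPA1B are near-identical copies, so reads of one may be counted for the other. HSP90AA1 was at 14393 ± 6705 against 8801 ± 1041. The heat shock call was lost without ICs replicate 2 (0.175; median 0.21) or anti-CD3 replicate 3 (0.0964; median 0.04) and without ICs replicate 3 (0.0516; median -0.09). The median also moved to -0.04 without ICs replicate 4, to 0.53 without ICs replicate 1, to 0.21 without anti-CD3 replicate 2 and to 0.20 without anti-CD3 replicate 1, and it was 0.26 in edgeR and 0.20 under quantile normalization. Stress and dying cell genes rose with a median of 0.47, 14 of 19 higher (camera adjusted p = 0.00721; adjusted p = 0.541 with an estimated correlation). DDIT4, a stress-induced brake on mTOR, was at 4068 ± 1551 against 2210 ± 1311, and MT2A, a metal-binding protein of a family with similar copies, at 9107 ± 7197 against 3550 ± 1237. This call was lost without ICs replicate 2 (0.289; median 0.07) or anti-CD3 replicate 3 (0.223; median 0.21), and the median was 0.75 without ICs replicate 1. In subject 1 both groups were lower with ICs, with medians of -0.71 and -0.85.

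T cell activation genes rose with a median of 0.13, 22 of 35 higher (camera adjusted p = 0.0306; 0.075 with the subject as a block, and adjusted p = 0.711 with an estimated correlation). CTLA4, an inhibitory receptor of activated T cells, was at 514 ± 248 against 248 ± 133, while MYC, a driver of growth, was at 2002 ± 986 against 4018 ± 2020. CD69, an early activation marker, had a log2 fold change of 0.13 ± 0.45 (SE), IL2RA, the high-affinity IL-2 receptor chain, 0.62 ± 0.72, IL2 1.46 ± 1.22, IFNG -1.05 ± 1.19 and CD28 0.09 ± 0.27. The activation call was lost without ICs replicate 2 (0.874; median -0.07) or 4 (0.12; median 0.03) or anti-CD3 replicate 3 (0.927; median 0.06). The median was 0.64 without ICs replicate 1, 0.27 without anti-CD3 replicate 1, 0.23 without anti-CD3 replicate 4 and 0.38 in edgeR. Keratins, filament proteins of epithelia, rose with a median of 0.69, 10 of 12 higher (camera adjusted p = 0.0306; adjusted p = 0.541 with an estimated correlation). KRT5 was at 70.0 ± 108 with ICs against 9.63 ± 12.5. The keratin call was lost without ICs replicate 3 (0.45; median -0.25), the library with the olfactory receptor reads, or 4 (0.0729), and without anti-CD3 replicate 1 (0.151; median 0.06) or 2 (0.0788). Leaving out ICs replicate 1 or 2 or anti-CD3 replicate 3 gave keratin medians of 1.48, 1.17 and 1.11, and edgeR gave 1.52.

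The other 15 lists did not pass for ICs against anti-CD3. Cholesterol synthesis had a median of 0.08 (adjusted p = 0.0579; 0.0253 with only genes of 2 or more exons) and Toll-like receptors and nucleic acid sensing one of -0.27 (0.0609). The remaining 13 had adjusted p between 0.194 and 0.962. Their medians were 0.73 for matrix metalloproteinases, -0.40 for cytokines and chemokines, 0.59 for platelet and erythroid markers, 0.44 for B cell markers, -0.10 for ribosomal proteins, 0.21 for follicular helper genes and -0.14 for helper lineage genes. They were 0.15 for the cell cycle, 0.09 for E3 ubiquitin ligases, 0.03 for monocyte markers, -0.03 for naive and quiescence genes, -0.08 for glycolysis and -0.12 for the unfolded protein response. Among these, median, mean and test direction differed in sign for E3 ubiquitin ligases, monocyte markers, naive genes and the unfolded protein response. Cell cycle genes had medians of -1.08, -1.43, 3.37 and 0.46 in subjects 1 to 4. They passed as higher without ICs replicate 2 (0.0181, median 0.67) or anti-CD3 replicate 1 (1.46e-05, median 0.60), and as lower without anti-CD3 replicate 3 (4.56e-05, median -0.56). With 1 library left out 7 more of the 15 passed. As lower these were cytokines without ICs replicate 2 (0.00159, median -0.76) or anti-CD3 replicate 3 (0.000224, median -1.02), helper lineage genes without the same libraries (0.00805 with a median of -0.17 and 0.0176 with one of -0.47), and Toll-like receptors without ICs replicate 1 (0.0271, median -0.36) or 2 (0.0134, median -0.19). Ribosomal proteins passed as lower without ICs replicate 1 (0.00168, median -0.23) or 2 (0.00369, median -0.16) or anti-CD3 replicate 2 (0.0016, median -0.16) or 4 (0.0108, median -0.16). As higher they were cholesterol synthesis without ICs replicate 3 (6.64e-07, median 0.40) or 4 (0.0229, median 0.22) or anti-CD3 replicate 1 (0.000965, median 0.13) or 4 (0.0113, median 0.25), follicular helper genes without ICs replicate 3 (0.0346, median 0.23) and metalloproteinases without ICs replicate 1 (0.0482, median 0.88). With the block, members passed adjusted over the list alone in the helper lineage (3), follicular helper (2) and E3 ubiquitin ligase (1) lists, where none did without it. SOCS3, a feedback inhibitor of cytokine signalling, was at 380 ± 371 against 959 ± 654, and TIGIT, an inhibitory receptor, at 457 ± 210 against 774 ± 174.

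No single gene of the 13679 tested passed limma over all genes for ICs against anti-CD3. The 4 genes with the smallest p among those lower were PRR5L, a partner of the mTOR complex (149 ± 22.9 with ICs against 423 ± 163; log2 fold change -1.45 ± 0.30), BST2 (-0.74 ± 0.18), EXOC6B (-1.21 ± 0.31) and MGST1 (-3.17 ± 0.81). Among those higher they were H1F0, a linker histone of resting cells (413 ± 201 against 111 ± 34.0; 1.81 ± 0.44), REG4 (1.24 ± 0.33), SNHG7 (1.02 ± 0.29) and NKD2 (2.27 ± 0.66). All 8 had a limma adjusted p of 0.996. At an unadjusted p under 0.05, limma gave 216 genes (78 higher, 138 lower) and limma with the block 1011 (420 higher, 591 lower). The balance turned in the other tools: edgeR gave 355 (243 higher, 112 lower), edgeR with the block 1138 (718 and 420) and DESeq2 748 (585 and 163). After adjustment the first 4 gave 0 genes and DESeq2 gave 2, both lower: PRR5L (adjusted p = 0.00666) and EXOC6B (adjusted p = 0.0400).

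**Figure D2:**
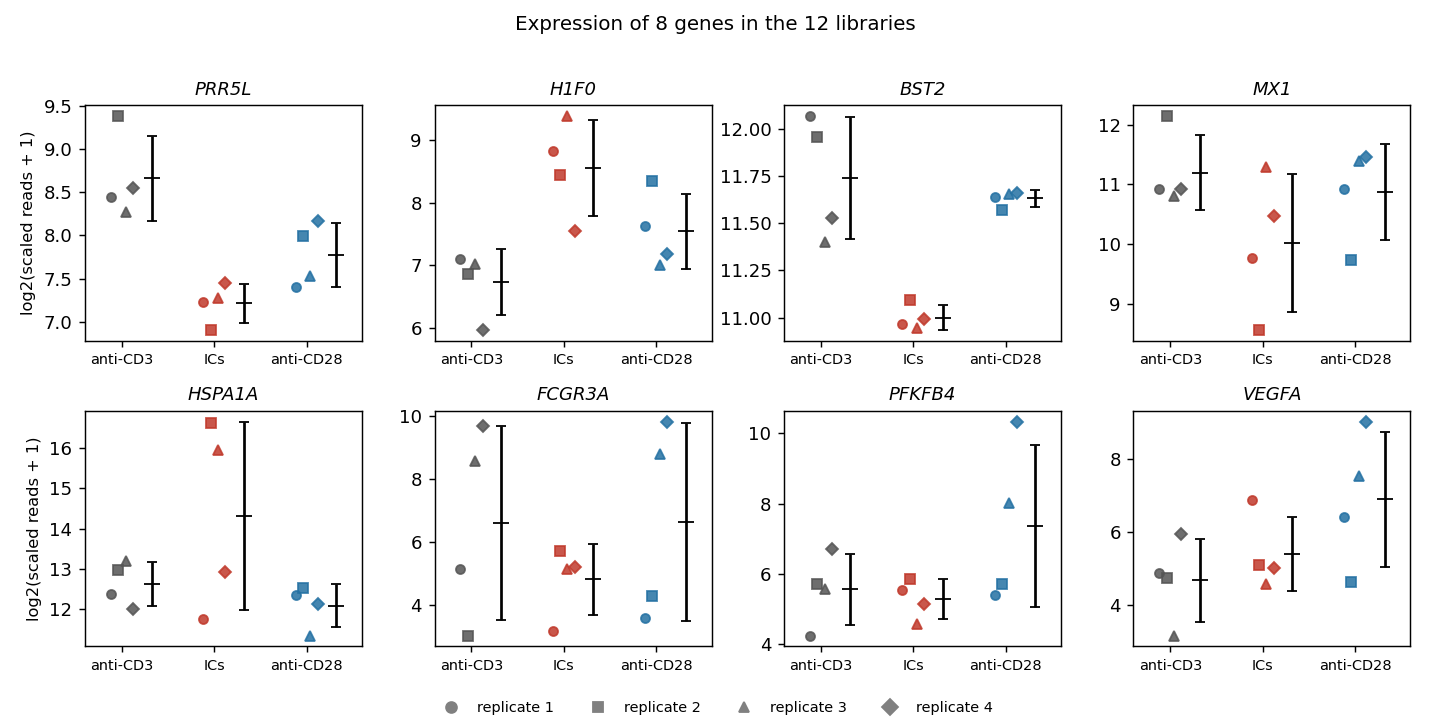
Levels of 8 genes in the 12 libraries, as log2(scaled reads + 1). Symbols are the 4 replicates and the bars show mean ± SD (n = 4). BST2 lies between 10.9 and 11.1 in the ICs libraries and at 11.4 or higher in the others.

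Anti-CD28 against anti-CD3 asks what classical costimulation added. Over all genes the median log2 fold change was -0.10, and list medians are given with it subtracted in brackets. Glycolysis genes rose with anti-CD28: 16 of 24 were higher, with a median of 0.23 [0.32] (camera adjusted p = 6.2e-05; adjusted p = 0.428 with an estimated correlation). PFKFB4, an enzyme that speeds glycolysis, was at 41.3, 51.8, 257 and 1284 in anti-CD28 replicates 1 to 4 and at 55.0 ± 35.4 with anti-CD3. ALDOC, a glycolytic aldolase, was at 1470 ± 767 against 692 ± 176 and was higher in 4 of 4 subjects. The list's median was -0.0045, -0.18, 0.65 and 0.60 in subjects 1 to 4. It was no longer called without anti-CD28 replicate 1 (0.054) or anti-CD3 replicate 3 (0.0919; median 0.15), and the median was 0.39 without anti-CD28 replicate 2 and 0.41 in edgeR.

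Cholesterol synthesis genes rose with a median of 0.18 [0.27], 17 of 22 higher (camera adjusted p = 0.00469; adjusted p = 0.926 with an estimated correlation). INSIG1, a sterol sensor, was at 1201 ± 364 against 789 ± 230. The cholesterol call was lost without anti-CD28 replicate 1 (0.321; median 0.11) and without anti-CD3 replicate 2 (0.0652) or 3 (0.517; median 0.05). The median was 0.10 without anti-CD28 replicate 2, 0.28 without anti-CD28 replicate 3, 0.27 without anti-CD3 replicate 1 and 0.29 without anti-CD3 replicate 4, and it was 0.30 in edgeR and 0.27 under quantile normalization. Ribosomal protein genes rose with a median of 0.11 [0.20], 30 of 38 higher, which was -0.01 under quantile normalization (camera adjusted p = 0.00884; adjusted p = 0.926 with an estimated correlation). RPL38 was at 14028 ± 1792 against 11389 ± 4064. The ribosomal call was lost without anti-CD28 replicate 1 (0.111) or 3 (0.217) and without anti-CD3 replicate 2 (0.855; median 0.0059) or 4 (0.772; median 0.02), and the median was 0.25 without anti-CD3 replicate 3 and 0.17 in edgeR.

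Heat shock proteins fell with anti-CD28, with a median of -0.29 [-0.20] and 24 of 28 lower (camera adjusted p = 0.00935; adjusted p = 0.926 with an estimated correlation). HSPH1, a partner of HSP70, was at 689 ± 213 against 1097 ± 162, lower in 4 of 4 subjects. Its log2 fold change ran from -0.95 without subject 3 to -0.50 without subject 1. HSPA5, the chaperone of the endoplasmic reticulum, had a log2 fold change of -0.39 ± 0.23, which was -0.63 without subject 3 and -0.18 without subject 2. Leaving out anti-CD28 replicate 1 (0.054) or anti-CD3 replicate 1 (0.439) ended the call. B cell markers rose with a median of 0.12 [0.21], 6 of 9 higher, and follicular helper genes with a median of 0.06 [0.15], 10 of 19 higher (camera adjusted p = 0.0421 each; adjusted p = 0.428 each with an estimated correlation). CD79A, a chain of the B cell receptor, was at 203 ± 169 against 43.1 ± 21.6, and SLAMF6, a receptor of follicular helper cells, at 1374 ± 216 against 980 ± 357.

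The B cell call was lost without anti-CD28 replicate 1 (0.179; median 0.46) or 4 (0.643; median -0.68) and without anti-CD3 replicate 1 (0.12; median -0.25) or 2 (0.174). Its median was 0.46 without anti-CD28 replicate 2, 0.28 without anti-CD28 replicate 3, 0.47 without anti-CD3 replicate 3 and 0.45 without anti-CD3 replicate 4, and it was 0.81 in edgeR and 0.34 under quantile normalization. The follicular helper call was lost without anti-CD28 replicate 1 (0.182; median 0.13), 2 (0.164) or 4 (0.0719; median -0.0080), and without anti-CD3 replicate 2 (0.0652), 3 (0.504) or 4 (0.071). Its median was 0.35 without anti-CD28 replicate 3, 0.31 without anti-CD3 replicate 1, 0.02 without anti-CD3 replicate 3 and 0.14 under quantile normalization. With only genes of 2 or more exons the B cell and follicular helper lists had adjusted p = 0.0536 and 0.0544, and by ranks both had 0.0872. Leaving out anti-CD28 replicate 1 left 0 lists past the threshold in place of 6, and leaving out anti-CD3 replicate 2 left 2.

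The other 18 lists had adjusted p between 0.0905, for the type I interferon response (median -0.31, 32 of 34 lower), and 0.906, for keratins. The interferon median was -0.02, -1.72, 0.38 and -0.14 in subjects 1 to 4, so it rested on subject 2: it was 0.05 without anti-CD28 replicate 2, with the direction turned (0.332), -0.15 without anti-CD3 replicate 2, -0.16 without anti-CD3 replicate 4 and -0.06 in edgeR. It passed without anti-CD28 replicate 3 (0.00321, median -0.57) or 4 (0.0169, median -0.50) or anti-CD3 replicate 3 (0.0266), and without anti-CD3 replicate 1 the median was -0.61.

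The cytotoxic list had no settled direction for anti-CD28 against anti-CD3. Its median was -0.04 with all libraries, and it lay at 0.84 without anti-CD28 replicate 1, 0.17 without 2, -0.49 without 3 and -0.74 without 4, and at -0.22, -0.48, 0.21 and 0.70 without anti-CD3 replicates 1 to 4. The list passed as higher without anti-CD28 replicate 2 (0.0365) or anti-CD3 replicate 4 (0.0041). The CD8 median was -0.0019 and ran from -0.66 without anti-CD28 replicate 3 to 0.44 without anti-CD28 replicate 1, and it did not pass in any of these 8 fits. Cell cycle genes (median 0.03) passed as higher without anti-CD28 replicate 2 (4.72e-05, median 0.44) or anti-CD3 replicate 1 (4.03e-06, median 0.48) and as lower without anti-CD3 replicate 3 (4.85e-09, median -0.59). Cytokines (median -0.51) passed as lower without anti-CD28 replicate 2 (0.00584) or anti-CD3 replicate 3 (1.67e-06, median -0.84). Without anti-CD3 replicate 3 the unfolded protein response passed as lower (0.019). Without anti-CD3 replicate 1, T cell activation (0.00849, median -0.03), helper lineage genes (0.0419, median 0.21) and stress genes (0.0419, median 0.11) passed as higher. Test direction differed in sign from median, mean or both for the cytotoxic, monocyte, T cell activation, naive, CD8, chemokine receptor, Toll-like receptor and keratin lists, none of which passed with all 12 libraries. No member of a list passed adjusted over the list alone, with or without the block.

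Among single genes, VEGFA, an angiogenic factor induced by low oxygen, was at 204 ± 223 with anti-CD28 and 30.5 ± 22.0 with anti-CD3 (log2 fold change 2.23 ± 0.89). BNIP3L, a mitophagy receptor, was at 2497 ± 1473 against 1215 ± 339 (0.90 ± 0.38; 0.56 without anti-CD28 replicate 4). ACYP1 (0.84 ± 0.30) and NADK, the kinase that makes NADP (1.22 ± 0.51), completed the 4 genes of smallest p among those higher. Those lower were PRR5L (223 ± 56.5 against 423 ± 163; -0.88 ± 0.30), AEN, a nuclease induced by p53 (-0.96 ± 0.37), IRAK1, a kinase of Toll-like receptor signalling (-0.81 ± 0.31), and PIK3CD, the lymphocyte PI3-kinase (-0.47 ± 0.18). All 8 had a limma adjusted p of 1.00, and limma called 0 genes. At an unadjusted p under 0.05 limma gave 38 genes (21 higher, 17 lower), limma with the block 273 (150 and 123), edgeR 75 (39 and 36), edgeR with the block 278 (161 and 117) and DESeq2 155 (85 and 70). All 5 gave 0 after adjustment. CD28 itself had a log2 fold change of 0.34 ± 0.27, IL2 -0.64 ± 1.22, IL2RA -0.12 ± 0.72 and CD69 0.41 ± 0.45.

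ICs against anti-CD28 asks how the 2 additions to anti-CD3 differed. Cytotoxic markers were lower with ICs in 21 of 21 cases and fell as a group, with a median of -1.73 (camera adjusted p = 2.33e-12; adjusted p = 0.368 with an estimated correlation). GZMA, a granule protease, was at 1258 ± 799 with ICs against 4975 ± 1798 with anti-CD28, and GNLY at 1503 ± 2339 against 6989 ± 7852. The median was -0.73, 0.10, -2.58 and -2.95 in subjects 1 to 4, and -1.10 without anti-CD28 replicate 4. None of its members passed adjusted over the list alone, and 5 did with the block. CD8 markers moved with them, 8 of 8 lower, with a median of -1.01 (camera adjusted p = 0.00785; adjusted p = 0.536 with an estimated correlation). The CD8 call was lost without ICs replicate 1 (0.178; median -0.36) or 4 (0.0744) and without anti-CD28 replicate 3 (0.127; median -0.55), and the median was -1.58 without anti-CD28 replicate 1. In the CD8 list 0 members passed adjusted over the list alone, and 2 with the block.

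Of the groups that were higher with ICs than with anti-CD28, heat shock proteins had the smallest p: 24 of 28 were higher, with a median of 0.58 (camera adjusted p = 2.29e-07; adjusted p = 0.384 with an estimated correlation). HSPA1A was at 43852 ± 46715 against 4550 ± 1436, HSPA1B at 4801 ± 4938 against 262 ± 129, HSPA6 at 2347 ± 3285 against 34.1 ± 52.9, and HSP90AA1 at 14393 ± 6705 against 6721 ± 2296. BAG3, a partner of HSP70, was at 1701 ± 485 against 1020 ± 265 and was higher in 4 of 4 subjects. In subject 1 the median was -0.18, and without ICs replicate 1 or 3 the median over all was 0.92 or 0.35. Stress genes rose with a median of 0.42, 14 of 19 higher (camera adjusted p = 0.0284; adjusted p = 0.630 with an estimated correlation). BBC3, a death protein induced by p53, had a log2 fold change of 1.25, which was 0.76 without subject 3 and 1.68 without anti-CD28 replicate 2. The stress call was lost without ICs replicate 2 (0.746; median 0.20) and without anti-CD28 replicate 3 (0.229) or 4 (0.151).

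The type I interferon response fell, with a median of -0.55 and 32 of 34 lower (camera adjusted p = 3.07e-07; adjusted p = 0.573 with an estimated correlation). BST2 was at 2048 ± 96.3 against 3173 ± 94.5 and OAS1 at 252 ± 106 against 474 ± 166, both lower in 4 of 4 subjects. The median was negative in each subject (-0.80, -0.69, -0.27 and -0.25), and it was -0.11 without ICs replicate 2 and -0.31 without anti-CD28 replicate 3. Toll-like receptors and nucleic acid sensing fell with a median of -0.27, 15 of 23 lower (camera adjusted p = 0.0438; adjusted p = 0.384 with an estimated correlation; 0.105 with only genes of 2 or more exons). AIM2, a sensor of cytosolic DNA, was at 61.0 ± 50.1 against 135 ± 98.0. Its log2 fold change ran from -1.64 without ICs replicate 2 to -0.72 without anti-CD28 replicate 2. TLR9, which senses DNA in endosomes, had a log2 fold change of -0.15, which was 0.31 without anti-CD28 replicate 4. The Toll-like receptor call was lost without ICs replicate 3 (0.327) or 4 (0.0856) and without anti-CD28 replicate 1 (0.0969), 2 (0.0538) or 3 (0.0561), and its median was -0.15 without ICs replicate 2, -0.42 without ICs replicate 1 and -0.45 under quantile normalization.

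Glycolysis genes were lower with ICs than with anti-CD28, with a median of -0.37 and 18 of 24 lower (camera adjusted p = 0.000426; adjusted p = 0.466 with an estimated correlation). Against anti-CD3 their median was -0.08 with ICs, which did not pass, and 0.23 with anti-CD28. SLC2A1, the glucose transporter GLUT1, was at 2346 ± 251 against 3220 ± 415, and PFKFB4 at 40.3 ± 14.9 against 408 ± 592. The median was -0.17 without ICs replicate 2 or anti-CD28 replicate 4 and -0.60 without anti-CD28 replicate 2. Ribosomal protein genes were lower with ICs as well, with a median of -0.19 and 33 of 38 lower (camera adjusted p = 0.000379; adjusted p = 0.630 with an estimated correlation). Their median against anti-CD3 was -0.10 with ICs, which did not pass, and 0.11 with anti-CD28. RPS9 was at 9612 ± 3161 against 13110 ± 1409 and was lower in 4 of 4 subjects. This call was lost without ICs replicate 3 (0.327; median -0.09) or 4 (0.0856), and the median was -0.30 without ICs replicate 1, -0.10 without anti-CD28 replicate 3, -0.12 in edgeR and -0.10 under quantile normalization.

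Chemokine and other G-protein-coupled receptors fell with a median of -0.27, 19 of 25 lower (camera adjusted p = 0.00785; adjusted p = 0.202 with an estimated correlation), a call lost without ICs replicate 3 (0.0864). Their median was -0.07 without ICs replicate 2, -0.42 without ICs replicate 1 or anti-CD28 replicate 1, -0.40 without anti-CD28 replicate 2 and -0.41 without ICs replicate 4, and it was -0.11 in edgeR and -0.42 under quantile normalization. In limma 1 member passed adjusted over the list alone, with or without the block. That held without ICs replicate 1 or anti-CD28 replicate 4 (adjusted p = 0.0477 and 0.0367) and was lost without any of the other 6, at 0.053 to 0.134. GPR183, a receptor that guides lymphocytes to oxysterols, was at 1540 ± 482 against 1963 ± 128. CX3CR1 belongs to the cytotoxic list as well, so the fall of the receptors is not fully independent of that list. Keratins rose with a median of 1.15, 10 of 12 higher (camera adjusted p = 0.0297; adjusted p = 0.630 with an estimated correlation). KRT86 was at 46.0 ± 33.9 with ICs against 20.3 ± 17.7, and KRT5 at 70.0 ± 108 against 6.01 ± 2.94. The keratin call was lost without ICs replicate 2 (0.0689) or 3 (0.327; median 0.02), and without anti-CD28 replicate 1 (0.092), 2 (0.0538) or 3 (0.121), and the median was 1.99 without ICs replicate 1 and 1.73 in edgeR.

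**Figure D3:**
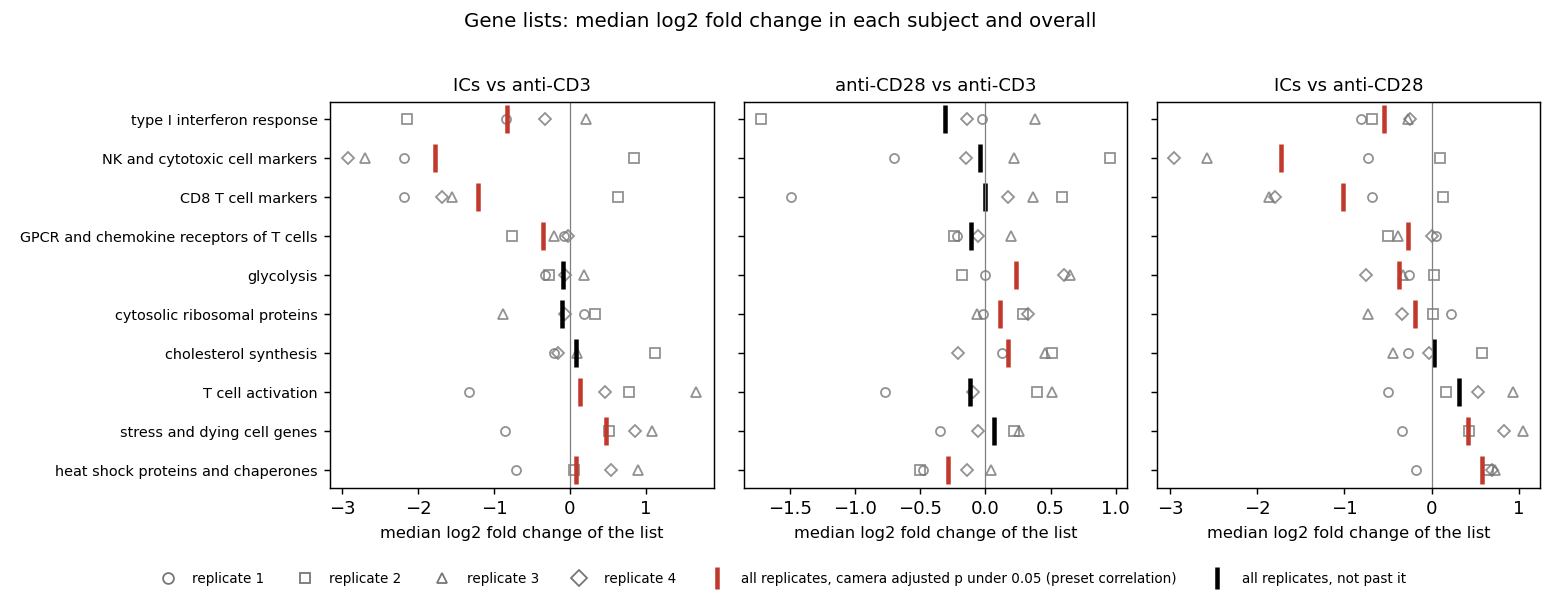
Median log2 fold change of 10 gene lists in each comparison. Open symbols are the 4 subjects. Bars are all replicates together, red where camera with the preset correlation had an adjusted p under 0.05 and black elsewhere. The cytotoxic list lies at -1.78 for ICs against anti-CD3 and at -1.73 against anti-CD28 (-1.10 without anti-CD28 replicate 4).

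The other 14 lists had adjusted p between 0.0872, for the Fc receptor list (median -0.11), and 0.942, for the naive and cytokine lists. T cell activation had a median of 0.32 and adjusted p = 0.137 (0.0412 with only genes of 2 or more exons). It passed as higher without ICs replicate 1 (0.000447, median 0.83) or anti-CD28 replicate 2 (0.00659, median 0.50), its median was 0.15, 0.12 and 0.17 without ICs replicates 2 to 4, 0.16 without anti-CD28 replicate 1 and 0.19 without 3, and the test's direction turned without ICs replicate 2. With 1 library left out 4 more of the 14 passed: cholesterol synthesis as lower without ICs replicate 2 (0.000405, median -0.25) and as higher without ICs replicate 3 (0.00646, median 0.19), cell cycle genes as higher without anti-CD28 replicate 1 (0.0434, median 0.22), and the Fc receptor list as lower without ICs replicate 2 (0.0449, median -0.09). The 4th was the helper lineage list (median -0.18), lower without ICs replicate 2 (0.00507, median -0.42) or anti-CD28 replicate 3 (0.00681, median -0.22) or 4 (0.0151, median -0.20). Median, mean and test direction differed in sign for the follicular helper, monocyte, cholesterol synthesis, naive and cytokine lists. With the block 2 members of the helper lineage list passed adjusted over the list alone, and none did without it. HOPX, a regulator of memory T cells, was at 96.0 ± 64.7 against 353 ± 196.

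Single genes of small p that were lower with ICs than with anti-CD28 included SLFN13, an RNase (223 ± 28.3 against 455 ± 58.5; log2 fold change -1.03 ± 0.25), PI16 (-2.10 ± 0.55) and GSDMD, the pore-forming protein of pyroptosis (1338 ± 214 against 2305 ± 405; -0.78 ± 0.21). Those higher were ACBD7 (1.96 ± 0.60), the small RNA SNORA74A (1.80 ± 0.55), ST13, a cochaperone of HSP70 (2983 ± 1134 against 1692 ± 150; 0.76 ± 0.24), and FBRS (0.84 ± 0.27). Limma called 0 genes (adjusted p of 1.00 for all 7). At an unadjusted p under 0.05 it gave 221 genes (79 higher, 142 lower). Most were higher in the other tools: limma with the block gave 1149 (675 and 474), edgeR 736 (617 and 119), edgeR with the block 1255 (820 and 435) and DESeq2 1486 (1301 and 185). The first 4 tools gave 0 genes after adjustment and DESeq2 gave 1, HSPA1B (log2 fold change 4.28 ± 0.87 in DESeq2, adjusted p = 0.0110). Limma with weights per library gave 531, of which 272 were higher and 259 lower, with the weights resting on replicate 4 (ICs 6.01, anti-CD28 3.91).

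Whether ICs and anti-CD28 shared a response was asked from their log2 fold changes against the same anti-CD3 libraries. PRR5L was lower with both additions (-1.45 and -0.88), in 4 of 4 subjects each. Across genes, which are not independent replicates, Pearson's r of the 2 fold changes was 0.12 and their covariance 0.0311. Unchanged groups simulated against the same controls gave r = 0.503 and a covariance of 0.289. The difference in covariance was thus -0.258 (-0.102 with the subject as a block). With the block the simulated covariance was 0.133. A part of the -0.258 therefore comes from subject differences, which the simulation without the block leaves in. With separate pairs of control libraries for each comparison, the covariance lay between -0.425 and -0.0227 over the 6 splits. The controls of the 2 comparisons then came from different subjects, while the treated groups held all 4. Subject differences push that covariance down whatever the response, so it cannot show that the responses differ. With the 2 comparisons made on different subjects the covariance lay between -0.26 and 0.0561, above 0 in 3 of 6 splits. At an unadjusted p under 0.05, 4 genes were higher and 1 lower in both comparisons and 0 went opposite ways, where independent lists give 0.12 and 0.172. With the block these were 46, 24 and 0, against 4.61 and 5.31 for independent lists. The shared controls alone raise such overlaps. No gene passed adjustment in both comparisons.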

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

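The single-library levels below were found by a fixed rule for samples far from the others, and the olfactory receptor reads by one for signal outside the comparisons; of the weighed explanations, those on genomic DNA, depth and fewer natural killer cells were chosen after the data had been examined and the others before. Chance sets apart about 1 in 20 groups of 4, and 7 of 186 groups held such a sample, where chance gives 9.3.

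IFNG was far lower in ICs replicate 1 (3.74 on the log2 scale) than in the other ICs libraries (7.99 to 8.77). The T cell activation list had a mean log2 level of 8.13 in anti-CD3 replicate 3, below the others of its group (9.39 to 9.53), and of 7.83 in ICs replicate 1, below the others of its group (9.82 to 10.0). Cytokines and chemokines were at 4.74 in ICs replicate 1 (others 7.32 to 7.69), and stress genes at 8.25 in the same library (others 9.25 to 9.45). Follicular helper genes were at 7.41 in anti-CD3 replicate 3 (others 8.12 to 8.22), and monocyte markers at 4.97 in anti-CD3 replicate 1 (others 6.11 to 6.32).

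The olfactory receptor genes, which enter no comparison as a group, took 12619 RPM (reads per 1e6 reads) in ICs replicate 3. Genomic DNA copied along with the RNA predicts reads mainly in genes of 1 exon, and there the ratio of silent 1-exon genes to those with 4 or more exons was 274 (32.3 against 0.118 RPM), which fits. The 0.118 RPM is 1 read of that library, so the size of the ratio is set by the lowest count that can be read. Transcription set off by ICs predicts a profile absent from the subject's anti-CD3 library, but Spearman's rho with anti-CD3 replicate 3 was 0.871, against that explanation. Depth does not account for it either, since the library was the smallest (8.49 against a median of 11.8, in 1e6 reads). Keratins, called at the preset correlation, had a median of -0.25 against anti-CD3 without this library.

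Cytotoxic cell markers were lower with ICs than with anti-CD3. Genes that natural killer cells express and CD4 T cells do not had a median log2 fold change of -1.8 (-0.0099 in replicate 2), but 9 of these 13 belong to the list itself, so fewer natural killer cells stay untested. Scaling was excluded, as the highest median over 3 other scalings was -1.75, and so was any 1 ICs library, as the highest median was -1.27. Whether other cells or the T cells themselves changed is open.

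Heat shock genes were higher with ICs than with anti-CD28. Genomic DNA was tested by lowering each ICs value by the 90th percentile of silent 1-exon genes in its library. The median of the list went from 0.577, with 24 of 28 members higher, to 0.321, with 17 of 28 higher, and lay between -0.209 and 0.574 in the 4 subjects. The same step moved the median of all tested genes from 0.0198 to -1.69. It takes more than such DNA adds to most genes, so it cannot decide. As deposited, the 26 members with 2 or more exons had a median of 0.553, while DNA predicts reads mainly in genes of 1 exon. For those 26 members this argues against DNA as the main source, and for the other members a part played by DNA stays open. A single ICs library was excluded, since the lowest median of the list was 0.354 with 1 left out. Replicate 1 went the other way (HSPA1A at 3433 with ICs and 5294 with anti-CD3). Against anti-CD3 the median was 0.08 with ICs (19 of 28 higher) and -0.29 with anti-CD28 (24 of 28 lower). The anti-CD28 libraries thus carry a part of the difference. For the part on the side of ICs, a response to ICs and a difference in handling between cultures would give the same values, and no test here parts them.

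The 8 libraries of a comparison were regrouped in all 35 ways. Genes past the adjusted threshold were 0 in the real grouping, a count that any split reaches (35 of 35), so this count tests nothing. The highest other counts were 476 (ICs against anti-CD3), 32 (anti-CD28 against anti-CD3) and 341 (ICs against anti-CD28). At an unadjusted p under 0.05 the real counts were 216, 38 and 221, reached by 30, 29 and 25 splits, with highest other counts of 3588, 1892 and 4552. The highest splits kept all 4 pairs of a subject's libraries together for anti-CD28 against anti-CD3 and ICs against anti-CD28, and parted 2 of 4 for ICs against anti-CD3. Among the 7 other splits that part all 4 pairs of a subject's libraries, as the real one does, the highest were 1046, 64 and 243. Of these 7, the real count was reached by 5, 2 and 1. List counts of 9, 6 and 10 were reached by 17, 24 and 10 splits (highest other 15, 12 and 14), so regrouped libraries often gave as many lists. Of the 7 other splits that part all pairs, 5, 5 and 3 reached them. With the subject as a block only 8 swaps exist, so a share under 0.05 was impossible. The real counts there were 1011, 273 and 1149, against highest other counts of 2743, 372 and 972, with 4, 2 and 1 of the 8 swaps as large.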

How the results depend on the processing

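The alternatives with DESeq2, edgeR with the block, genes of 2 or more exons, the block without ICs replicate 3 and the block with an estimated correlation were added after seeing the data. Of the named-gene values under other settings, 1044 kept direction and side of the threshold, 20 became called (all with array weights, ICs against anti-CD28) and 9 reversed; with libraries or subjects left out, 1255 stayed and 53 reversed. No gene passed in any leave-one-out fit (0 to 0). The subject as a block changed no call other than those printed in the report. Depth limits low genes: FCGR3B, TLR7 and TLR8 could not be tested. The cause was not tested for any value below.

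Genes past the threshold were 2 for ICs against anti-CD3 and 1 for ICs against anti-CD28 in DESeq2, and 531 for the latter with array weights. Gene lists were 0 in all 3 comparisons with an estimated correlation, with or without the block. With 1 library left out they ranged from 5 (without ICs replicate 4) to 11 (without ICs replicate 1) for ICs against anti-CD3, 0 (without anti-CD28 replicate 1) to 8 (without anti-CD28 replicate 2) for anti-CD28 against anti-CD3, and 7 (without ICs replicate 3) to 11 (without ICs replicate 2) for ICs against anti-CD28. The covariance difference ranged from -0.44 to -0.11.

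With array weights these log2 fold changes reversed: TLR3 0.32, CD69 -0.061 and BCL6 -0.056 (ICs against anti-CD3), IFNG 0.037 (anti-CD28 against anti-CD3) and CD28 0.0035 (ICs against anti-CD28). Quantile normalization reversed SYK (0.13, anti-CD28 against anti-CD3) and TLR3 (-0.31, ICs against anti-CD28). EdgeR reversed BCL6 (0.15) and CCL5 (0.094), both ICs against anti-CD28.

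Leave-one-out ranges that crossed 0 were, for ICs against anti-CD3, CD28 -0.15 to 0.27, TLR3 -0.99 to 0.20, IL2 -0.18 to 2.96, IFNG -2.09 to 0.42, IL2RA -0.33 to 1.60 and CD69 -0.25 to 0.46. For anti-CD28 against anti-CD3 they were FCGR3A -1.17 to 1.05, SYK -1.35 to 0.77, FCER1G -1.11 to 0.36, IL2 -1.33 to 0.45, IFNG -1.71 to 0.60 and IL2RA -0.86 to 0.43. For ICs against anti-CD28 they were TLR3 -0.29 to 0.83, TLR9 -0.83 to 0.31, IFNG -1.35 to 0.65, CD69 -0.62 to 0.050 and BCL6 -0.36 to 0.21.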

Other observations

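The genes of these paragraphs were chosen after seeing the data, and no test was run on the choice. Values of 5 genes known to respond to low oxygen follow. BNIP3, a mitophagy receptor, was at 262, 155, 1181 and 2631 scaled reads in anti-CD28 replicates 1 to 4 and at 300, 341, 700 and 588 in the anti-CD3 libraries of the same subjects. VEGFA was at 85.0, 23.7, 184 and 524 with anti-CD28 and at 28.1, 25.5, 7.86 and 60.6 with anti-CD3. ENO2, a glycolytic enolase, was at 939, 1552, 2073 and 4795 against 807, 1223, 1245 and 1604, and ANKRD37, a target of the low-oxygen factor HIF1, at 18.5, 5.27, 70.2 and 142 against 16.9, 15.8, 24.7 and 62.7. PDK1, which turns pyruvate away from mitochondria, was at 142, 75.5, 551 and 504 against 86.5, 208, 367 and 338, so replicates 3 and 4 were the higher ones with anti-CD3 as well.

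Proliferation genes were low in anti-CD3 replicate 3. MKI67, a marker of dividing cells, was at 65.1 there and at 918 to 1945 in the other anti-CD3 libraries, and TOP2A, a topoisomerase of dividing cells, at 92.0 against 1320 to 3023. IL13 was at 5321, 2332, 25.8 and 54.2 in anti-CD3 replicates 1 to 4, and CSF2 at 3247, 621, 75.2 and 591. MT2A was at 1375, 5961, 10902 and 18190 in ICs replicates 1 to 4. CD79A was at 1074 in ICs replicate 1 and at 33.3 to 67.5 in the other ICs libraries.

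The deposited p-values were not adjusted for the number of genes. For ICs 260 genes had one under 0.05 and for anti-CD28 2540, and adjustment by Benjamini and Hochberg left 0 of each. Of the 2540, 1955 had no read in any of the 8 libraries, where the scaled value of an empty count differs with depth and gives each such gene the same deposited value of 0.0251. The deposited ratio was 4 or more for 1720 genes with ICs and 56 with anti-CD28. Of the 1720, 1645 were highest in ICs replicate 3, and 41.0% of those with annotation had 1 exon, against 6.08% of all annotated genes. In the workbook's keratin selection of 145 genes, 115 had a ratio of 2 or more and 109 of these were highest in ICs replicate 3.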
